A study of Mus musculus with 38 samples.

How the data were processed

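The data are single-cell RNA-seq counts of pancreatic cells from Rag1-deficient C57BL/6J mice. An adenovirus, Ad-M3C, carried Pdx1, Mafa and Neurog3 (Ngn3), the transcription factors that specify pancreatic endocrine and beta cells, into the pancreas, and an mCherry label marked infected cells. Infected, living cells were sorted 1, 2, 4, 6, 8 and 10 days later. Acinar cells of untreated mice, sorted on the viability dye alone, served as day 0. Per the labels, each cell carried a 16-bp barcode, each transcript a 9-bp molecular tag (UMI), amplification took 24 PCR cycles, and plates had 96 wells.

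The deposited table holds UMI counts per gene and cell for 15143 genes and 2641 cells. The values are whole numbers from 0, no columns are identical, and every gene is detected in at least 10 cells. The submitters' notes name Trim Galore, FastQC, STAR and the mouse build mm9. Versions, the annotation, the counting program and the filters that led to the 2641 cells are not given in the sources used here. Genes are identified by symbol alone, and positions were not used. A 9-bp tag tells 262144 molecules apart. The most UMIs of 1 gene in 1 cell were 243128 for Rn45s, a ribosomal RNA gene, 147489 for Gip and 88472 for Ins2, so counts near these values are compressed. Near-identical genes (Ins1 and Ins2, the trypsinogens, the amylases, Reg3 genes, Ifit3 and Ifit3b, H2 genes) share reads, and how these were assigned is not given in the sources used here. Nor is it given whether Pdx1, Mafa and Neurog3 counts come from the vector or from the chromosomal genes.

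Cells were assigned to 38 libraries, each a sample of the labels, by the day and number in the table's column names. Of these, 29 matched by day and number and 9 by day only, 6 of day 1 and 3 of day 6, which does not affect the groups. The column names also hold a date, taken as the library batch (A to H). Batch F holds the libraries of day 0 alone, and batches G and H those of day 1 alone, so that day and batch cannot be told apart for these days. Days 2, 4 and 6 share batches A, B and E in part, and days 6, 8 and 10 share C and D in part. Age and the sex of the mice also differ between days. The libraries were treated as replicates; whether 1 mouse gave more than 1 library is not given in the sources used here. Their numbers do not pair libraries across days.

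Cells needed at least 500 detected genes, which removed 0 cells since the lowest number was 1452. Raw counts were summed per library, which needed at least 10 cells. The sums were analysed with edgeR 4.0.16 in R 4.3.3: filterByExpr with the day as group, TMM scaling, a quasi-likelihood fit of all 7 days together with no covariates, and Benjamini-Hochberg adjusted p below 0.05. Levels are CPM, edgeR's counts per unit of TMM-scaled library size, as mean ± SD over libraries. Log2 fold changes are those of the fit, with ± as their standard error. Folds are ratios of mean CPM. Where all libraries of a day were at 0, the fold is a lower bound against 3 counts over the summed scaled library sizes of that day, which covers counting error only. No fold is given where a day had 1 to 3 counts. Day 0 libraries hold most of their UMIs in a few genes, so scaling matters: TMM factors were 0.187 to 0.247 at day 0 against 1.53 to 1.76 over days 4 to 10.

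Of the contrasts, 6 set a day against day 0 and 5 set a day against the sampled day before it. Transient genes were higher at day 1, 2, 4 or 6 than at both day 0 and day 10. In a further comparison, cells of each day 4 or day 10 library were ranked by their share of insulin UMIs, the raw counts of the upper and lower tercile were summed, and the sums were compared within libraries without Ins1 and Ins2. Single-cell measures used 2511 cells thinned to 20000 UMIs each and were compared between days by exact two-sided permutation tests on library values. With 5 against 5 libraries the smallest p is 0.00794. Adjustment was over the day comparisons of a measure.

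Fixed before the data were examined were these tests, 24 gene lists, 8 marker lists of other cell types, and the rule for naming genes. The lists cover acinar enzymes and secretory products, acinar transcription factors, the vector-encoded factors, insulin and granule cargo, glucose sensing and exocytosis, endocrine transcription factors, endocrine progenitor genes, other islet and gut hormones, ductal markers, pancreatic injury and acute phase, interferon response, MHC class I presentation, unfolded protein response, p53 targets, DNA methylation enzymes, proliferation, immediate early and heat shock, beta-cell disallowed genes, the Notch pathway, YAP targets, apoptosis regulators, fatty acid and amino acid catabolism of acinar cells, cytosolic ribosomal proteins and oxidative phosphorylation. The marker lists cover macrophages and dendritic cells, neutrophils, lymphoid and NK cells, endothelial cells, mesenchymal and stellate cells, mesothelial cells, Schwann cells and erythroid cells. Members absent from the table under the symbols listed were left out. Lists were tested with camera in limma 3.58.1 (preset correlation 0.01, voom values), adjusted over the lists of a contrast, with an estimated correlation and fry as alternatives.

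By the naming rule, the vector factors and insulin genes were always named. For day 1 and day 10 against day 0 it names the 12 largest rises and 12 largest falls among called genes with at least 50 CPM on the higher day and no overlap between libraries. For steps it names 4 and 4, for transient genes 12, and for insulin-high against insulin-low cells 10 and 10 with the same sign in each library. List members may be named by the size of their change, and members that did not pass with their values. Of the genes so named, the text gives the ones with a function clause in full and the rest by name. For 4 of the genes so named the result is not reported here.

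The sort held other cells than acinar-derived ones. Cells were clustered with leidenalg and igraph, with neighbours from scikit-learn (2000 variable genes, 30 components, 15 neighbours, Leiden resolution 1), which gave 17 clusters. A cluster was named after a marker list when at least 3 of its 50 leading genes belonged to it, with exceptions. A cluster mostly of day 4 had 4 ductal markers but shared 7 leading genes with an acinar-like cluster, and stayed unnamed. Another, with 5 cargo and 6 hormone genes, stayed unnamed because its first 10 held more hormone than cargo genes. An exploratory clustering with other settings had been looked at first. The unnamed cluster with ductal markers was kept, and an alternative leaves it out as the further cluster of uncertain type. With the clusters in view, 5 were set aside: macrophage-like, mesenchymal-like, a pair of ductal-like ones, and islet-like cells of mainly days 1 and 2. The other 12 clusters, with 1997 cells, are called retained clusters, and every comparison was repeated on them. In that set 3 libraries fall below 10 cells, leaving 6 at day 1 and 4 at day 2. This choice was made after seeing the data. No test between clusters is reported. Doublets were not called.

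The procedure was tested on simulated counts with the depth and spread of these libraries. For day 10 against day 0 (13520 genes, 50 changed by each fold) it found 40% of genes raised 2-fold, 68% raised 4-fold, 28% lowered to 0.5 and 76% lowered to 0.25, with 4 false calls. For paired classes of day 10 cells (10665 genes) the shares were 42%, 86%, 32% and 48%, with 5 false calls. Changes of 2-fold are therefore often missed. Of 4 simulated lists of 20 genes, the raised one was called and the 3 unchanged ones were not. Simulated genes were drawn independently of each other, whereas the acinar enzyme list had an estimated correlation of 0.827 at day 10. The simulated lists therefore cannot show how often the preset correlation calls a list of correlated genes falsely. Outside the changed genes all simulated libraries had the mean profile of day 10, so the different make-up of day 0 counts was not simulated. These results thus do not bear on errors from scaling in contrasts with day 0.

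Alternatives fixed in advance were DESeq2 1.42.0 (its size factors, and its Wald test), no scaling factor, no low-count filter, no cell filter, at least 1500 detected genes, cells thinned before summing, leaving out cells with at least 3 markers of other cell types, leaving out the acinar enzymes and insulin genes, library numbers as a replicate block, leaving out each library, other insulin thresholds, another depth, and the upper and lower quartile in place of terciles. Added after the data were seen were the retained clusters, the same without a further cluster of uncertain type, leaving out Rn45s and mitochondrial genes, batch as a term over days 2 to 10, day 1 from batch G or H alone, and fits of the compared days alone. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1, statsmodels 0.14.6, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9.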

Results

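Single cells were profiled on the path from pancreatic acinar cells, which make digestive enzymes, toward insulin-expressing cells. The table holds 5 libraries of untreated acinar cells (day 0, 262 cells), 8 libraries of day 1 after the virus (292 cells), and 5 libraries each of day 2 (322 cells), day 4 (404), day 6 (442), day 8 (460) and day 10 (459). Cells had 5416 to 1172886 UMIs, with a median of 83770 UMIs and 4187 genes. Library totals ranged from 5906837 to 7973442 UMIs at day 0, from 2132120 to 5988131 at day 1, from 3823469 to 7803716 at day 2, from 5214265 to 10080816 at day 4, from 5253626 to 9632204 at day 6, from 8948542 to 11911620 at day 8, and from 9462362 to 12159891 at day 10. Rn45s, a ribosomal RNA gene, took 36.6% ± 1.74 of the UMIs at day 0, 20.5% ± 9.72 at day 1 and 2.19% ± 0.24 at day 10. The 30 acinar enzyme genes of the table took 43.0% at day 0, so that 2 kinds of transcript held most of the untreated counts. All levels below are CPM on TMM-scaled library sizes, unless stated otherwise.

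The sorted cells changed in make-up over time. Macrophage-like cells were 0 of 262 cells at day 0, which allows a share of up to 1.15%. They made up 1.80% ± 1.53 of the cells of a library at day 1 (n = 8), 41.1% ± 12.3 at day 2, 33.0% ± 13.0 at day 4, 17.2% ± 5.39 at day 6, 8.65% ± 2.74 at day 8 and 2.16% ± 1.27 at day 10 (n = 5 each). Mesenchymal-like cells were 42 of 292 at day 1 and 57 of 322 at day 2, and no more than 2 on any other day. Ductal-like cells were 63 at day 1 and 26 at day 10. Retained clusters held 258, 171, 127, 263, 354, 403 and 421 cells in order of day. Comparisons below are given for all cells, and beside them for the retained clusters, a set chosen after the data were seen. It leaves out the islet-like cells and keeps insulin-rich clusters of late days, so endocrine calls in it cannot replace calls that fail in all cells.

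**Figure D1:**
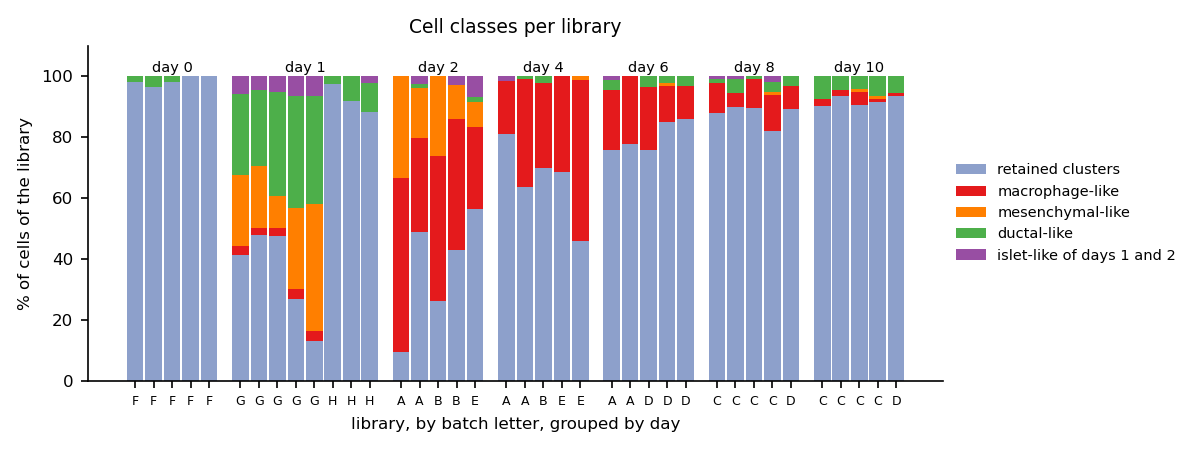
Share of the cells of each library (percent, vertical axis) in retained clusters and in the macrophage-like, mesenchymal-like, ductal-like and islet-like clusters, with libraries in order of day and marked by batch letter. Macrophage-like cells reached 41.1% on average at day 2.

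The first question is what the virus and its factors changed within 1 day. Pdx1, which directs pancreas and beta-cell formation, was at 19.7 ± 10.1 CPM (n = 5) in untreated libraries and 2466 ± 1093 (n = 8) at day 1, 125-fold higher (log2 6.97 ± 0.44, edgeR adjusted p = 6.83e-16). Mafa, a regulator of insulin transcription, was at 0 in all untreated libraries and at 41.5 ± 28.3 CPM at day 1, at least 96.1-fold higher (adjusted p = 2.60e-06). Neurog3, which starts endocrine differentiation, went from 0 to 28.0 ± 13.2 CPM, at least 64.7-fold higher (adjusted p = 6.52e-05). The vector-encoded list was called higher with 3 of 3 members (camera adjusted p = 0.011, adjusted p = 0.0976 with an estimated correlation, and 0.0137 in the retained clusters). Ins2 was at 2410 ± 5281 CPM at day 0 and 5465 ± 7378 at day 1, and Ins1 at 493 ± 1079 and 2079 ± 2762, neither of them a difference larger than the spread between libraries. Without day 0 replicate 2 both rose, by log2 7.64 for Ins1 and 6.81 for Ins2, but the rise sat in batch G, where Ins2 was at 1935 to 20958 CPM, and not in batch H, at 0 to 48.5. In the retained clusters, which leave out the islet-like cells, Ins2 was at 70.4 ± 66.0 CPM at day 0 and 33.3 ± 29.3 at day 1, so no rise was seen.

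Interferon-induced genes rose most at day 1. Ifit3, an antiviral protein, was at 0 in every untreated library and at 1969 ± 411 CPM at day 1 (at least 4559-fold). Iigp1, an immunity-related GTPase, rose from 0 to 1262 ± 377 (at least 2922-fold), and Serping1, a complement inhibitor, from 0 to 668 ± 589 (at least 1546-fold). Mx1, which blocks viral replication, reached 311 ± 96.7 CPM and Zbp1, a sensor of foreign nucleic acid, 313 ± 143, both from 0. Ifit3b, F830016B08Rik, Gbp7, Cd74, Apol9b, Oasl1 and Ifi44 completed the 12 largest rises, each at least 559-fold and each from 0. All 31 interferon genes were higher over all genes tested and 31 adjusted over the list alone (camera adjusted p = 1.08e-30, adjusted p = 0.000273 with an estimated correlation). The 31 were also higher in batch G alone and in batch H alone, and in the retained clusters. MHC class I presentation had 13 of 14 genes higher and 1 lower (adjusted p = 2.43e-12, and 0.0287 with an estimated correlation). Its peptide transporter Tap1 rose from 2.78 ± 1.86 to 446 ± 156 CPM and the light chain B2m from 30.7 ± 7.71 to 1260 ± 663.

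Genes of the secretory acinar cell fell at day 1. Fkbp11, a secretory-pathway isomerase, fell from 760 ± 37.0 to 22.0 ± 9.85 CPM (34.5-fold lower), and Derl3, which clears misfolded proteins, from 152 to 3.89 (39.0-fold). Rbpjl, the acinar partner of Ptf1a, fell from 550 ± 85.2 to 21.1 ± 13.7 (26.1-fold lower, log2 -4.72 ± 0.62, edgeR adjusted p = 8.28e-08). Sostdc1, Hamp2, Padi2, Shank1, Casp9, Macrod1, Egf and 1810018F18Rik were the other large falls. Of the acinar enzymes 28 of 30 were lower (28 adjusted over the list alone; camera adjusted p = 6.40e-31, and 0.0396 with an estimated correlation; median log2 -2.18, and -0.48 without scaling). Acinar transcription factors were lower in 6 of 7 (adjusted p = 4.02e-05, adjusted p = 0.0588 with an estimated correlation), although their median of -1.53 becomes 0.41 without scaling. Bhlha15, which builds the secretory apparatus, went from 372 to 16.6 CPM and Ptf1a, the master factor of acinar cells, from 112 to 18.8.

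Stress genes split by program at day 1. The cell-cycle inhibitor Cdkn1a rose from 154 ± 25.6 to 1134 ± 390 CPM (log2 2.88 ± 0.21), and p53 targets had 14 of 20 genes higher and 2 lower (camera adjusted p = 0.000483, and 0.0396 with an estimated correlation). The acute-phase protein Lcn2 rose from 0.766 to 1088 ± 404 CPM and the antibacterial lectin Reg3g from 546 to 11760 ± 7162, while the injury list as a whole, with 7 of 13 higher and 1 lower, was not called (adjusted p = 0.119). Herpud1, an endoplasmic reticulum stress gene, fell from 1302 to 95.4 CPM, and the unfolded protein response had 18 of 24 genes lower and 4 higher (adjusted p = 1.77e-14, and 0.00309 with an estimated correlation), though its median of -1.42 becomes 0.51 without scaling. Ribosomal proteins were lower in 74 of 80 (median -1.46, but 0.47 without scaling; adjusted p = 9.02e-81) and oxidative phosphorylation genes in 58 of 78 (median -0.92, but 1.02 without scaling; adjusted p = 8.02e-25). Fatty acid and amino acid catabolism of acinar cells was lower in 12 of 12 (adjusted p = 2.15e-16). Ductal markers were higher in 11 of 20 and lower in 1 (adjusted p = 0.00117, adjusted p = 0.117 with an estimated correlation), with Spp1, a ductal matrix protein, rising from 321 to 3624 ± 2322. YAP targets (6 of 7 higher, adjusted p = 0.0107), apoptosis regulators (11 of 15 higher, 1 lower, adjusted p = 0.0107) and beta-cell disallowed genes (9 of 18 higher, adjusted p = 0.0161) were called by camera with the preset correlation but not with an estimated one. The retained clusters differed for some lists. There the injury list was called (6 of 11 higher, camera adjusted p = 0.000222, but 0.0789 with an estimated correlation). Endocrine progenitor genes were called too (7 of 11 higher, 1 lower, camera adjusted p = 0.0306, but 0.143 with an estimated correlation). With an estimated correlation ductal markers (0.0217) and acinar transcription factors (0.0186) passed and p53 targets did not (0.0540).

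In total 3686 genes were higher and 2243 lower at day 1 among 14147 tested, and 2690 and 1891 among 13378 in the retained clusters, with 4052 called in the same direction in both sets. The balance of higher and lower calls rests on the scaling. Of the called genes 62.2% were higher, against 98.2% without a scaling factor, and the median of all genes moved from log2 0.34 to 2.17. Day 1 and day 0 libraries share no batch, so day and batch cannot be told apart in this contrast.

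**Figure D2:**
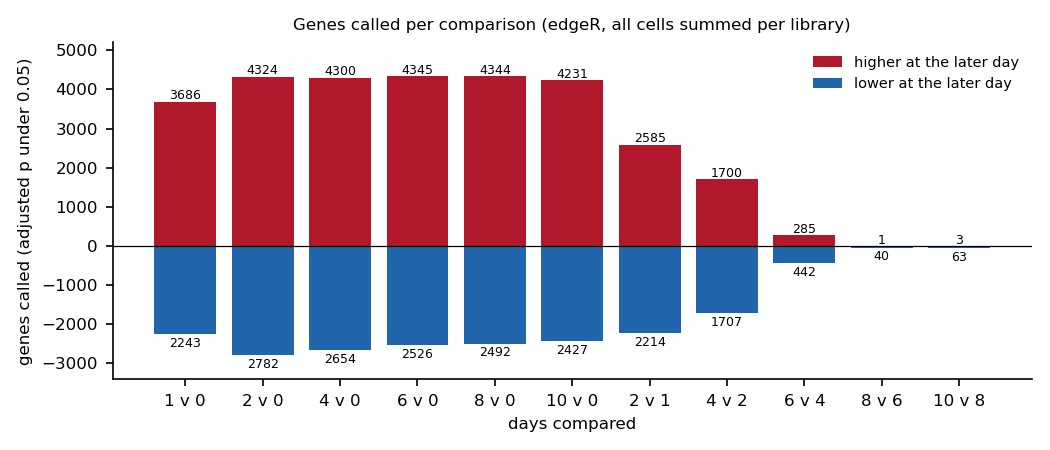
Number of genes called higher and lower in each contrast (edgeR, adjusted p below 0.05), for all cells summed per library. Against day 0, the genes called higher ranged from 3686 at day 1 to 4345 at day 6. Those called lower ranged from 2243 at day 1 to 2782 at day 2. The last step, day 10 against day 8, had 3 higher and 63 lower.

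At day 2, interferon genes were still far above the untreated level, with 31 of 31 higher (camera adjusted p = 3.2e-18, and 0.0075 with an estimated correlation) and 30 of 31 higher in the retained clusters. Pdx1 was at 523 ± 241 CPM, Mafa at 5.42 ± 6.45 and Neurog3 at 35.9 ± 54.4. Of the acinar enzymes, 29 of 30 were lower. All 14 macrophage and dendritic markers, 10 of 10 mesenchymal markers and 5 of 5 mesothelial markers were higher, so that counts of this day mix cell types. No endocrine list was called in all cells. Among retained cells endocrine transcription factors were higher in 8 of 15 (camera adjusted p = 0.020), insulin and granule cargo in 11 of 16 (0.041) and progenitor genes in 8 of 11 (0.0070), none of them with an estimated correlation. Against day 0, 4324 genes were higher and 2782 lower, and 3457 and 2375 in the retained clusters, with 4618 shared in direction.

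At day 4, endocrine lists were called in all cells too. Endocrine transcription factors were higher in 13 of 15 (camera adjusted p = 0.00019, adjusted p = 0.11 with an estimated correlation), and in the retained clusters in 12 of 15 (0.015 with an estimated correlation). Glucose sensing and exocytosis had 15 of 22 genes higher (adjusted p = 0.0002) and insulin and granule cargo 9 of 16 (adjusted p = 0.0098), and neither passed with an estimated correlation in all cells, while in the retained clusters 16 of 22 and 13 of 16 were higher and both passed (0.015 each). Without a scaling factor the calls of transcription factors and granule cargo in all cells were lost (adjusted p = 0.165 and 0.737). Ins2 in the retained clusters was at 70.4 ± 66.0 CPM at day 0 and 351 ± 209 at day 4 (log2 2.32 ± 0.65, adjusted p = 0.0029). Of the interferon genes 30 of 31 were still higher. Against day 0, 4300 genes were higher and 2654 lower, and 4133 and 2570 in the retained clusters, with 6013 shared.

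Days 6 and 8 extended this. In the retained clusters Ins2 reached 4495 ± 1668 CPM at day 6 (log2 6.00 ± 0.76) and 17664 ± 3943 at day 8. Insulin and granule cargo was higher there in 14 of 16 on both days, and glucose sensing in 18 of 22 at day 6 and 19 of 22 at day 8. Over all cells cargo was higher in 10 of 16 on both days (camera adjusted p = 0.000364 and 9.12e-05), which was lost with an estimated correlation (0.356 and 0.314) and without scaling (0.802 and 0.675). Glucose sensing, with 17 and 18 of 22, was lost with an estimated correlation (0.121 and 0.0924). In all cells, 4345 genes were higher and 2526 lower at day 6, and 4344 and 2492 at day 8. The retained clusters gave 4319 and 2461 at day 6, and 4383 and 2447 at day 8, with 6073 and 6162 genes shared in direction with all cells.

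By day 10 the hormone genes dominated the libraries. Gip, an incretin hormone of the gut, was at 0 in all untreated libraries and at 69899 ± 7293 CPM at day 10, at least 1.62e+05-fold higher, and held 11% ± 1.13 of all UMIs. Ins2 reached 36925 ± 3612 CPM against 2410 ± 5281 at day 0 (log2 3.94 ± 1.65, edgeR adjusted p = 0.048), and Ins1 3171 ± 671 against 493 ± 1079, which did not pass (adjusted p = 0.16). The call of Ins2 was lost without any 1 of the other 9 libraries (adjusted p = 0.0571 to 0.0935). In the counts, day 0 replicate 2 carried nearly all of the untreated insulin counts. Without that library Ins1 rose by log2 8.26 and was called. In the retained clusters, which leave out its cell with the most insulin, Ins2 rose from 70.4 ± 66.0 to 34805 ± 4207 CPM (495-fold, log2 8.95 ± 0.86, adjusted p = 1.90e-11) and Ins1 from 14.9 ± 14.0 to 3085 ± 728 (206-fold, log2 7.69 ± 0.74). Pdx1 was at 626 ± 58.9 CPM (31.8-fold, log2 4.99 ± 0.41), Neurog3 at 19.4 ± 14.9 (at least 44.8-fold) and Mafa at 1.66 ± 0.57 (at least 3.84-fold, adjusted p = 0.038, a call lost in 7 of the 10 runs without 1 library).

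Other genes that rose most by day 10 came from 0 in all untreated libraries. Amelx, an enamel matrix protein, reached 1229 ± 711 CPM (at least 2845-fold), Nefm, a neurofilament, 531 ± 69.6 (at least 1230-fold), Th, which makes catecholamines, 366 ± 34.5 (at least 848-fold), and Gfra3, a neurotrophic receptor, 150 ± 13.5 (at least 348-fold). Serping1, 1700086L19Rik, Rasgrf2, St8sia5 and 6330403K07Rik were also among them. The prohormone convertase Pcsk2, in the retained clusters, rose from 0 to 2285 ± 236 CPM (at least 5379-fold), G6pc2, the islet glucose-6-phosphatase, from 0 to 744 ± 99.6 (at least 1752-fold) and Rfx6, an islet transcription factor, from 0 to 280 ± 22.6 (at least 658-fold). The glucose transporter Slc2a2 rose from 3.53 to 192 ± 18.3 CPM in all cells, and the endocrine factor Neurod1 from 7.77 to 364 ± 22.9 (log2 5.55 ± 0.61).

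Digestive enzymes were among the largest falls. Pnlip, pancreatic lipase, fell from 120101 ± 13941 to 51.8 ± 81.6 CPM (2319-fold lower, log2 -11.18 ± 1.29, edgeR adjusted p = 4.17e-09). The carboxypeptidases Cpb1 (121505 ± 8556 to 88.6 ± 116 CPM, 1372-fold lower) and Cpa1 (88770 ± 9716 to 73.8 ± 72.6, 1203-fold lower) and the elastase Cela3b (1535-fold lower) fell alike. Hamp2, a hepcidin, went from 264 ± 40.7 to 0.0112 CPM, Tmed11 from 236 to 0.064 and 1810018F18Rik from 95 to 0.0559. Reg3d, 2210010C04Rik, Dmbt1, Zg16 and Rnase1 were the other large falls. Of the acinar enzymes 29 of 30 were lower (29 adjusted over the list alone, median log2 -8.86, and -5.93 without scaling; camera adjusted p = 3.83e-38, and 0.0426 with an estimated correlation). Acinar transcription factors were lower in 6 of 7 (adjusted p = 1.30e-05, adjusted p = 0.0732 with an estimated correlation), with a median of -2.41 that becomes 0.52 without scaling; the retained clusters gave 0.00209 with an estimated correlation.

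Endocrine lists were higher at day 10. Glucose sensing and exocytosis had 18 of 22 genes higher (19 adjusted over the list alone; camera adjusted p = 1.40e-07), insulin and granule cargo 11 of 16 with 1 lower (adjusted p = 6.24e-05) and endocrine transcription factors 13 of 15 (adjusted p = 0.000198). None of the 3 passed with an estimated correlation in all cells (adjusted p = 0.109, 0.305 and 0.125), which the values of the retained clusters (0.00209, 0.00209 and 0.0284) do not replace, as that set was chosen with the insulin-rich clusters in view. Without a scaling factor glucose sensing kept its call in all cells (0.00108), whereas granule cargo and transcription factors lost theirs (0.537 and 0.242). Chga, a granule protein, rose from 42.7 to 8617 ± 446 CPM and the prohormone processor Cpe from 34.4 ± 10.2 to 1721 ± 73.9. Nkx6-1, a factor of mature beta cells, rose from 0.678 to 7.04 CPM. Of the other hormones 7 of 11 were higher, but the list was not called (adjusted p = 0.102). Ghrl, the ghrelin gene, reached 864 ± 720 CPM, Pyy 346 and Gast 73.2, whereas Gcg, at 1.05 CPM, did not pass, and neither did Sst and Ppy.

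Several other programs were lower at day 10 relative to the median gene. Ribosomal proteins were lower in 75 of 80 (median log2 -2.25, but 0.66 without scaling; camera adjusted p = 2.11e-92, and 0.000151 with an estimated correlation), as were 15 of 24 genes of the unfolded protein response, with 4 higher (median -0.88, but 2.04 without scaling; adjusted p = 3.39e-08, and 0.0426 with an estimated correlation). Fatty acid and amino acid catabolism was lower in 10 of 12 (adjusted p = 2.86e-13, and 0.00278 with an estimated correlation). Oxidative phosphorylation had 31 of 78 genes lower and 11 higher (median -0.26, but 2.66 without scaling; adjusted p = 8.94e-06, adjusted p = 0.305 with an estimated correlation). Ductal markers had 9 of 20 lower and 2 higher (median -1.22, but 1.69 without scaling; adjusted p = 0.0258), the injury list 6 of 13 lower and 2 higher (adjusted p = 0.0216), beta-cell disallowed genes 10 of 18 lower and 4 higher (adjusted p = 0.0229) and the Notch pathway 5 of 9 lower and 1 higher (adjusted p = 0.0305). None of these 4 lists passed with an estimated correlation. Reg2, an injury-induced secreted lectin, fell from 42980 to 50.2 CPM and the Notch effector Hes1 from 115 to 15.9. Not called were interferon response (15 of 31 higher, 1 lower, adjusted p = 0.163), MHC class I (10 of 14 higher, 1 lower, 0.101), p53 targets (8 of 20 higher, 4 lower, 0.754), endocrine progenitor genes (6 of 12 higher, 2 lower, 0.53), DNA methylation enzymes (3 of 7 higher, 2 lower, 0.73), proliferation (2 of 24 higher, 5 lower, 0.718), immediate early and heat shock genes (4 of 18 higher, 6 lower, 0.335), YAP targets (1 of 7 lower, 0.557), apoptosis regulators (6 of 15 higher, 4 lower, 0.53) and the vector-encoded list (3 of 3 higher, 0.218). Of these, the retained clusters called MHC class I (9 of 14 higher, 1 lower, adjusted p = 0.0282, but 0.313 with an estimated correlation).

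Over all genes, 4231 were higher and 2427 lower at day 10, and 4345 and 2486 in the retained clusters, with 6163 shared in direction. Of the called genes 63.5% were higher, against 98.3% without scaling, and the median of all genes moved from log2 0.44 to 3.28. Libraries of day 0 and day 10 share no batch, so day and batch cannot be told apart here either.

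**Figure D3:**
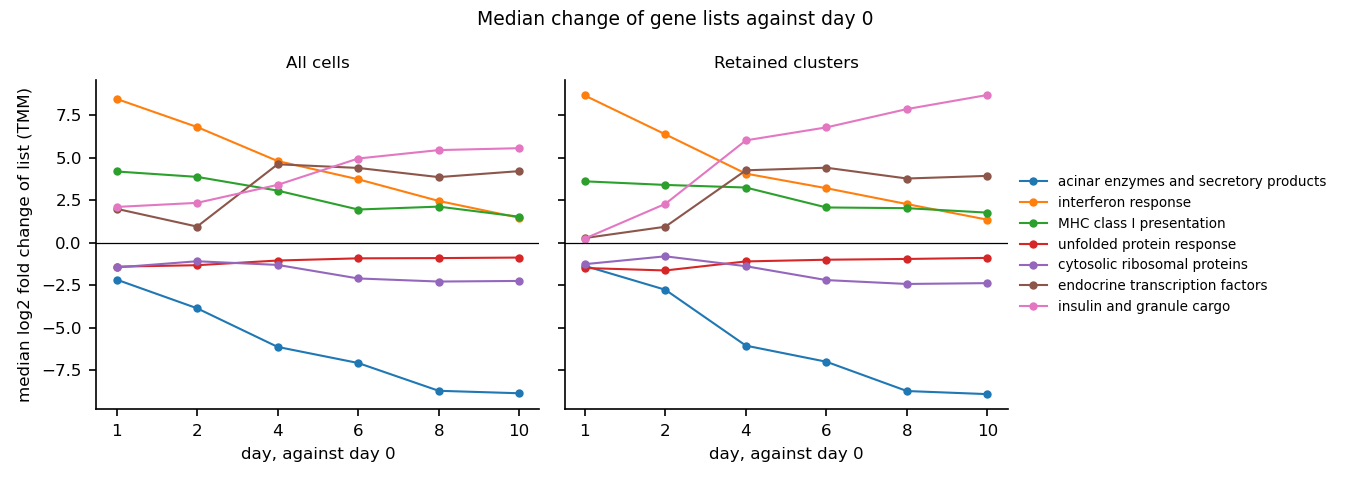
Median log2 fold change against day 0 of gene lists on each day, scaled by TMM, for all cells and for the retained clusters, with genes that are at 0 in a whole day taken at their bound. Acinar enzymes ended at -8.86 in all cells at day 10 and at -5.93 without scaling, whereas the day 10 medians of ribosomal proteins and the unfolded protein response are above 0 without scaling.

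The steps between sampled days show when each program moved. From day 1 to day 2, Pdx1 fell to 523 ± 241 CPM (log2 -2.24 ± 0.33, edgeR adjusted p = 2.02e-06) and Mafa from 41.5 to 5.42 CPM (log2 -2.93 ± 0.72, adjusted p = 0.0018). Macrophage-like cells, which hold little Pdx1, rose at this step. The retained clusters gave smaller falls, from 2648 ± 1257 to 876 ± 167 CPM for Pdx1 (log2 -1.60 ± 0.29) and from 55.0 ± 27.6 to 10.8 ± 10.3 for Mafa (log2 -2.35 ± 0.62). Folr2 and Ccl12, expressed by macrophages, rose from 0.225 to 66.0 ± 47.7 CPM and from 1.46 to 138, with Ccl9 rising from 0.90 to 146 ± 60.3 and Cldn15 from 0.453 to 50.4. Pigr, the immunoglobulin transporter of epithelia, fell from 290 ± 67.5 to 12.0 ± 12.8 (24.1-fold lower), and AA986860, Mmp7 and Sftpd fell besides. The granule gene Chga in the retained clusters rose from 18.0 to 821 ± 852 CPM (45.6-fold) and insulin and granule cargo was higher in 12 of 16. Interferon genes turned down, with 22 of 31 lower and 1 higher, and ribosomal proteins rose in 40 of 80 and fell in 1. In all, 2585 genes rose and 2214 fell, and 2093 and 1652 in the retained clusters, with 2437 shared.

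From day 2 to day 4, Gip rose from 293 ± 231 to 13997 ± 5273 CPM (47.8-fold, log2 5.58 ± 0.84, edgeR adjusted p = 9.87e-06), Slc2a2 from 3.97 to 128 ± 31.6 (32.2-fold, log2 4.98 ± 0.58), the liver and endocrine factor Onecut2 from 1.59 to 70.3 ± 16.1 (44.3-fold) and Amelx from 36.7 to 1210 ± 508 (32.9-fold). The mesothelial genes Upk3b and Dmkn fell from 220 to 0.716 CPM and from 375 to 1.45, and Tpm2 and Cd34 fell too. Pcsk2 in the retained clusters rose from 6.10 to 560 ± 128 CPM (91.8-fold) and Chgb, a granule protein, from 34.9 to 2649 ± 689 (76.0-fold), and the acute-phase gene Lcn2 fell from 379 to 8.72 (43.4-fold lower). Interferon genes were lower in 28 of 31 and acinar enzymes in 27 of 30. The step held 1700 rises and 1707 falls, and 1864 and 1393 in the retained clusters, with 1732 shared.

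From day 4 to day 6, Ghrl rose from 23.1 ± 28.9 to 352 ± 225 CPM (15.3-fold, log2 3.94 ± 0.74, edgeR adjusted p = 0.000608), and Il1r1 and Nnat by 5.83-fold and 5.73-fold. Sprr1a, a cornified-envelope protein, fell from 119 to 3.25 CPM (36.6-fold lower), Reg3g from 828 ± 93.5 to 84.7 ± 80.5 (9.78-fold), Ly6c2 from 171 to 12.0 and Ly6a from 551 to 39.6. Ins2 in the retained clusters rose by log2 3.68 ± 0.67 (adjusted p = 0.000235), Ins1 by 2.69 ± 0.56 (adjusted p = 0.0013) and G6pc2 from 42.3 to 270 ± 59.2 CPM. Ribosomal proteins were lower in 62 of 80 at this step. In all, 285 genes rose and 442 fell, and 492 and 522 in the retained clusters, with 600 shared. With batch as a term 194 genes were called, and Ghrl (log2 2.76, adjusted p = 0.189), Nnat (2.46, 0.0948), Sprr1a (-6.60, 0.107), Ly6c2 (-2.23, 0.180) and Reg3g (-2.42, 0.170) lost their calls.

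Few genes were called after day 6 in the fit of all days, while fits of the compared days alone gave 95 for day 8 and 239 for day 10. From day 6 to day 8, 1 gene rose and 40 fell (810 at an unadjusted p below 0.05), and in the retained clusters 4 and 51, with 27 shared. The enzymes Rnase1 (483 ± 602 to 37.5 CPM, edgeR adjusted p = 0.030) and 2210010C04Rik (602 ± 701 to 57.1, 0.0075), the scavenger protein Dmbt1 (194 ± 333 to 5.34, 0.0205) and Reg2 (336 ± 418 to 19.2, 0.0082) fell. All 4 calls were lost without day 6 replicate 1, where the log2 changes were -2.57, -2.40, -3.12 and -3.06. Rnase1 lost its call in 7 of the 10 runs without 1 library (adjusted p up to 0.240) and Dmbt1 in 5 (up to 0.252), and with batch as a term Dmbt1 and 2210010C04Rik shrank to log2 -0.36 and -0.10 and Reg2 and Rnase1 reversed to 0.27 and 0.18. Ins1 rose in the retained clusters (log2 2.37 ± 0.55, adjusted p = 0.032), and the rise of Ins2 did not pass (adjusted p = 0.297), although its levels of 2800 to 7007 and 10734 to 20081 CPM did not overlap. From day 8 to day 10, 3 genes rose and 63 fell (809 at an unadjusted p below 0.05), and in the retained clusters 1 and 5, with 5 shared. Lpl, lipoprotein lipase, rose from 73.5 ± 9.68 to 156 ± 3.44 CPM (2.12-fold, adjusted p = 0.0176). Ctss, a macrophage cathepsin, fell from 178 to 19.4, B2m from 768 ± 122 to 344 ± 43.0 (2.23-fold lower, adjusted p = 0.043), and Ldha, lactate dehydrogenase, from 50.5 to 24.6. Of the 10 runs without 1 library, 9 lost the call of B2m, 7 that of Ldha, 3 that of Lpl and 2 that of Ctss, although the log2 changes stayed between 1.01 and 1.09 for Lpl, -2.99 and -2.92 for Ctss, -1.24 and -1.08 for B2m and -1.06 and -0.97 for Ldha in those runs. The single riser of the retained clusters was Ucn3, a peptide of mature beta cells, from 11 ± 4.75 to 61.0 ± 22.0 CPM (5.55-fold, log2 2.47 ± 0.50, adjusted p = 0.032).

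**Figure D4:**
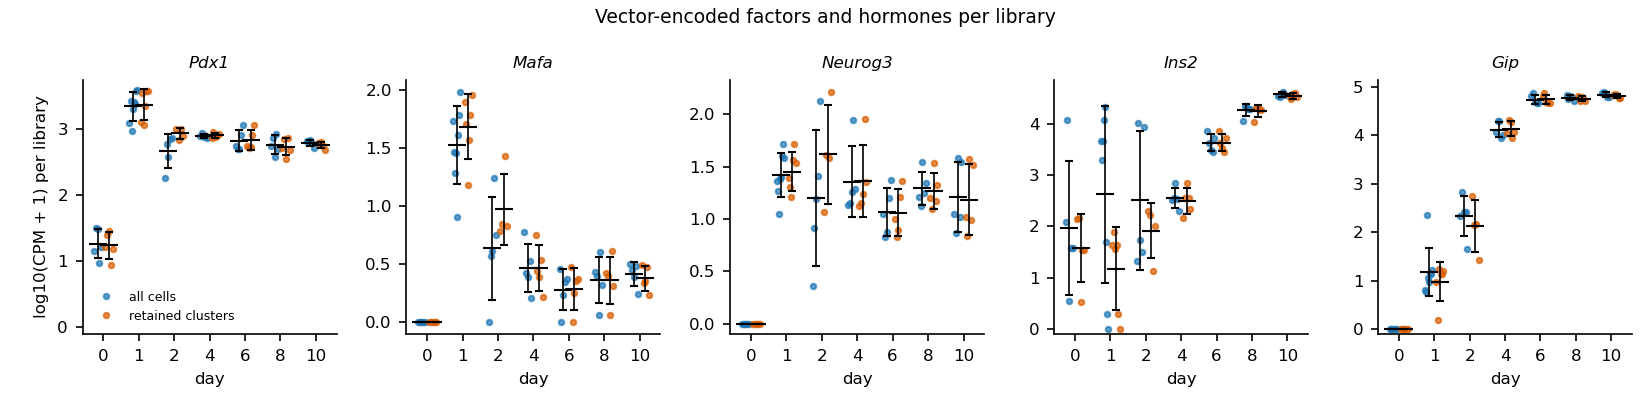
Levels of Pdx1, Mafa, Neurog3, Ins2 and Gip in each library by day, as log10 of CPM plus 1, for all cells and retained clusters, with the mean and SD of each day. In all cells Pdx1 peaked at 2466 CPM at day 1, and Gip rose from 0 at day 0 to 69899 CPM at day 10.

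Some genes were higher on the way than at both ends, though not all were back at the untreated level. Over all cells 2723 genes were higher at a day than at both day 0 and day 10, of which 878 were highest in fold at day 1, 1608 at day 2, 236 at day 4 and 1 at day 6. All 31 interferon genes were among them, beside 13 of MHC class I, 15 p53 targets and 14 macrophage markers. Iigp1 was at 1262 CPM at day 1 and at 0.125 at day 10. Ccl5, a chemokine, peaked at 325 ± 194 CPM at day 2, Ly6c2, a monocyte marker, at 438 ± 154 and the acute-phase gene Saa3 at 392. Ifit3b, Upk3b, Upk1b, F830016B08Rik, Nnmt, Slfn4, Lgals7 and Has1 were the others of the 12. The retained clusters gave 1923 transient genes, with all 31 interferon genes again. There the GTPase Gbp2 went from 507 to 0.278 CPM and Ifit3 from 1490 to 0.438, and Ifit3b, Iigp1, F830016B08Rik, Cxcl11, Gm4841, Gm12250, Ifi27l2a, Ifit1bl1, Ly6a and Ifi44 completed the 12.

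The share of insulin-expressing cells per day was measured in cells thinned to 20000 UMIs. Cells with at least 1% of their UMIs from Ins1 and Ins2 were 0.377% ± 0.844 at day 0 (n = 5), 3.22% at day 1, 0.887% at day 2, 1.13% ± 0.669 at day 4, 14.9% ± 6.17 at day 6, 34.8% ± 5.76 at day 8 and 57.7% ± 2.79 at day 10 (n = 5). Days 6, 8 and 10 were above day 0, and each of the steps from day 4 on was a rise, with 5 of 5 libraries above all 5 of the other day (exact permutation tests, adjusted p = 0.0175 each). In macrophage-like cells the share was 0% from day 2 to day 8. In the retained clusters the shares were 1.10% at day 4, 17.9% at day 6, 37.6% at day 8 and 59.3% at day 10. Within batches, the share rose from 1.60% at day 4 to 15.8% at day 6 in batch A, from 34.4% at day 8 to 56.6% at day 10 in batch C, and from 14.2% to 36.7% and 62.1% over days 6, 8 and 10 in batch D.

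A single insulin UMI is no measure of expression here. It was found in 14.1% ± 24.9 of cells at day 0, 47.6% ± 35.4 at day 1, 54.4% ± 40.3 at day 2, 50.5% ± 18.5 at day 4, 91.1% ± 7.22 at day 6, 98.6% ± 1.24 at day 8 and 99.5% ± 0.62 at day 10. Macrophage-like cells, thinned to the same depth, held one in 57.3%, 31.7%, 81.8% and 100% of cells at days 2, 4, 6 and 8 (1 library of 11 cells at day 8), so that at days 2 and 8 the share was not above this background. The steps from day 6 to day 8 and on to day 10 did not pass (exact permutation, adjusted p = 0.0873 and 0.252). For Gip at 1% of UMIs or more, the shares were 0% at days 0 and 1, 0.318% at day 2, 26.2% ± 8.03 at day 4, 57.7% ± 6.91 at day 6, 54.9% ± 4.52 at day 8 and 71.2% ± 3.43 at day 10.

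The acinar enzyme share of a cell measures how much of the starting program was left. Its median over cells was 42.5% ± 1.86 at day 0, 16.2% ± 15.9 at day 1, 6.95% ± 7.33 at day 2, 3.15% ± 1.82 at day 4, 1.30% ± 0.37 at day 6, 0.617% ± 0.105 at day 8 and 0.387% ± 0.051 at day 10. At day 1 the batches differed, with 4.95% in batch G and 34.9% in batch H. In the retained clusters the shares were 42.6% ± 1.89, 42.9% ± 7.71 (n = 6), 29.6% ± 2.55 (n = 4), 5.47% ± 0.68, 1.60% ± 0.60, 0.703% ± 0.124 and 0.394% ± 0.060, and no fall passed at day 1 (exact permutation, adjusted p = 0.924), where batch G was at 49.8% and batch H at 36.1%. Of the 171 retained cells of day 1, 166 were in 1 cluster named acinar-like for its enzyme genes, and 113 of the 127 of day 2 in another. A high share was thus in good part built into this set, and its test cannot decide on a fall. Yet 24 of 30 acinar enzymes were called lower there at day 1 after scaling (median log2 -1.37, but -0.044 without scaling), 11 in batch G and 23 in batch H. Whether the fall began at day 1 or day 2 rests on the scaling, the batch and the choice of clusters. Within batches, all cells of batch A went from 7.03% at day 2 to 4.12% and 1.71%, and batch E from 16.1% to 1.59%, but batch B from 2.28% to 4.34%.

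**Figure D5:**
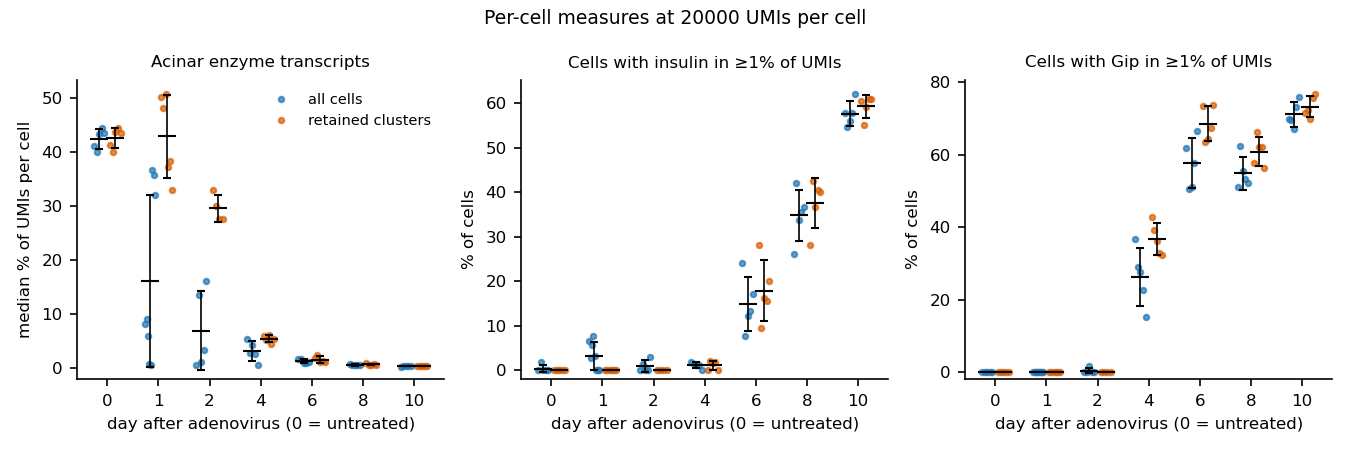
Acinar enzyme share (median percent of UMIs per cell), and percent of cells with at least 1% of UMIs from insulin genes and from Gip, per library and day at 20000 UMIs per cell, with mean and SD, for all cells and retained clusters. The insulin share rose from 1.13% of cells at day 4 to 57.7% at day 10.

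Whether the 2 programs exclude each other was asked within libraries, as a rank correlation over cells between the acinar enzyme share and the granule cargo share of the remaining UMIs. Over all cells the mean rho was -0.096 at day 1, 0.030 at day 2, 0.519 ± 0.198 at day 4, 0.212 at day 6, 0.128 at day 8 and -0.061 ± 0.168 at day 10, negative in 11 of 33 libraries (exact sign test, p = 0.080). Day 10 did not differ from day 4 or day 6 after adjustment (exact permutation, adjusted p = 0.0595 for both). Among retained clusters 22 of 30 libraries were negative with all days pooled (exact sign test, p = 0.016). No single day passed there, the lowest being day 6 with 5 of 5 libraries negative (exact sign test, adjusted p = 0.375). That set was chosen after the data were seen, with acinar and insulin-rich clusters in view, and all cells did not lean the same way. Whether the programs exclude each other is therefore not decided.

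Cells of a library with much and with little insulin were compared at the start and the end of insulin expression. At day 4 the insulin-high cells held a median of only 0.0175% to 0.065% insulin UMIs per library, near background, and 1 of 9990 genes was called (686 at an unadjusted p below 0.05). It was Amelx, at 3952 ± 1172 CPM in insulin-high and 179 ± 80.2 in insulin-low cells (log2 4.52 ± 0.27, edgeR adjusted p = 2.41e-05, higher in 5 of 5 libraries), and it was also the one gene called in the retained clusters. With the upper and lower quartile no gene was called, and in 1 library the insulin-high class held cells without an insulin UMI, so this call is weak.

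At day 10 the insulin-high cells held a median of 10.2% to 14.3% insulin UMIs and the insulin-low cells 0.025% to 0.06%. Among 10675 genes 854 were higher and 718 lower in insulin-high cells, and 765 and 701 among 10358 in the retained clusters. G6pc2 was at 2174 ± 295 against 256 CPM (log2 3.11 ± 0.13, edgeR adjusted p = 1.37e-09), the co-secreted peptide Iapp at 1890 against 223 (log2 3.46 ± 0.33), Ucn3 at 193 against 40.1, Slc2a2 at 459 against 112 and Nkx6-1 at 19.8 against 3.51 (adjusted p = 0.0089). By the naming rule the neuropeptide Gal (1501 ± 137 against 83.3 CPM), the phosphatase inhibitor Ppp1r1a (231 against 4.93), Fam107a (108 against 1.38), Amelx, Atp4a, Ttc28, Col6a3, Sct, Barhl1 and Cox6a2 were higher. Lower were Ghrl (139 against 4874 ± 4182 CPM, log2 -6.09 ± 1.00, adjusted p = 0.00076), the acinar factors Rbpjl (0.379 against 183 ± 71.4) and Ptf1a (1.24 against 134), the monoamine transporter Slc18a2 (2.19 against 349), the lipase relative Pnliprp1 (88.3 against 2687), Matn4, Ly6h, Galk1, Clps and the macrophage genes Lyz2 and C1qa. Of the lists, the unfolded protein response had 14 of 24 genes higher and 1 lower (17 and 1 adjusted over the list alone), oxidative phosphorylation 19 of 76 higher, and immediate early and heat shock genes 13 of 17 lower. Acinar enzymes were lower in 8 of 26 and higher in 2. Endocrine transcription factors were higher in 1 of 12 and lower in 2 (1 and 7 adjusted over the list alone, median log2 -0.35). Endocrine progenitor genes were higher in 1 of 10 and lower in 5. Insulin and granule cargo was higher in 5 of 13 and lower in 1, and glucose sensing and exocytosis higher in 8 of 21 and lower in 4. Both classes came from the same libraries, so batch does not enter this comparison. Their make-up differed, as macrophage-like cells were 3.33% to 6.67% of the insulin-low cells in 4 of 5 libraries and none of the insulin-high cells.

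Marker lists of other cell types were followed in unthinned cells, where a marker was present from 1 UMI on. The measure was the share of cells with at least 3 markers of 1 list. It was 0% at day 0 (0 of 262 cells), 66.0% at day 1, 97.7% at day 2, 94.1% at day 4, 62.4% ± 31.4 at day 6, 32.1% at day 8 and 24.9% at day 10. Retained clusters held a mean of 36.7% of the cells of a library at day 2 and 65.7% at day 4, so many retained cells carried such markers. The measure therefore does not count cells of other types, and background transcripts were not set apart. The batches of a day also differed, with 82.3% in batch G and 38.9% in batch H at day 1. At day 6 the shares were 95.9% in batch A and 40.1% in batch D, so day and batch are mixed in this course. Macrophage and dendritic markers were higher than at day 0 in 12 of 14 at day 1 and 13 of 14 at day 10, and in the retained clusters in 5 and 3. Between those days the retained clusters had 11 of 14 higher at day 2, 9 at day 4 and 7 at day 6, with 0 lower. At day 2, 5 of 6 mesenchymal and 2 of 2 mesothelial markers were also higher there, so that set was not free of such transcripts. At day 1, 2 of 2 neutrophil, 7 of 7 endothelial, 9 of 10 mesenchymal and 3 of 5 mesothelial markers were higher, against none of 2 Schwann and none of 1 erythroid marker. No lymphoid or NK marker was tested, as the table holds 1 of 8. By day 10, 1 of 7 endothelial, 1 of 10 mesenchymal and 0 of 5 mesothelial markers were higher. So were 1 of 2 neutrophil, 1 of 2 Schwann and 1 of 1 erythroid markers.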

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

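The tests on the untreated library, the doublet test and the tests on Gip were chosen after those results were seen; the batch and Pdx1 tests on macrophage-like cells were set before. An untreated library stood far from the other 4. In day 0 replicate 2, 58.5% of the cells had an insulin UMI (1.64% to 4.26% in the others) and 1.89% had at least 1% insulin UMIs (0% in the others). Its Ins1 level was 2423 CPM (0 to 24.5 in the others) and its Ins2 level 11856 CPM (2.47 to 118). A candidate source is 1 islet-like cell in the sort, although clustering placed it with ductal-like cells, since 98.8% of the library's 21237 insulin UMIs sat in 1 cell, with 30.9% insulin and 1.62% acinar enzyme UMIs. That cell held 651 Iapp, 305 Chga, 85 G6pc2, 28 Sst and 0 Gcg UMIs. In the other 52 cells, 48 held an insulin UMI, and they had 3.44 Iapp UMIs per 100 insulin UMIs against 3.10 in that cell, which is consistent with carry-over of its transcripts within the library but rests on 9 Iapp UMIs. No biological explanation was tested, as the design gives none within day 0. Without this library, Ins1 rose by log2 8.26 at day 10 and was called. Concentration in 1 cell was not particular to it. In replicates 1, 4 and 5 the highest cell held 99.0%, 96.4% and 98.5% of only 210, 56 and 68 insulin UMIs. In replicate 3 it held 33.3% of 3. The highest cells of replicates 1, 4 and 5 were in an acinar-like cluster, with at most 0.098% insulin UMIs.

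Other libraries stood apart from those of their day in a single gene. Mafa was at 16.6 CPM in day 2 replicate 4 (0 to 4.64 in the others). Neurog3 was at 132 CPM in day 2 replicate 5 (1.28 to 24.9 in the others) and at 88.0 in day 4 replicate 2 (12.7 to 18.5). Ins1 was at 175 CPM in day 4 replicate 1 (22.5 to 53.9) and at 1042 in day 6 replicate 1 (140 to 207). Ins2 was at 11206 CPM in day 8 replicate 1, below the 19234 to 21919 of the others. Gip was at 223 CPM in a day 1 library of batch G and at 4.93 to 15.9 in the other day 1 libraries. Chance singles out about 1 in 20 groups, or 3.6 of the 72 groups examined, and 11 were found. The groups are not independent, as the insulin measures of day 0 replicate 2 rest on 1 cell and count more than once. These numbers are therefore no test of an excess over chance.

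Macrophage-like cells made up 41.1% of the sorted cells of a library at day 2 and 33.0% at day 4, although the sort selected for mCherry. Doublets with an acinar-derived cell would hold a large part of its enzymes and more UMIs. Macrophage-like cells held a median acinar enzyme share of 5.12% of that of retained cells (1.96% to 8.41% over 10 libraries). Their median UMIs were 36645 against 118682, which argues against such doublets within this cluster only. The cluster was formed by expression, so a low enzyme share was in part built in, and doublets placed in other clusters remain open. A batch effect is argued against by batch A, with 44.1% of cells at day 2, 26.3% at day 4 and still 21.1% at day 6, and by the fall from 14.5% to 1.11% within batch D, though in batch E the share was 26.8% at day 2 and 42.2% at day 4. Pdx1 was at 38.4 CPM in them against 1110 in retained cells; as carried-over RNA it would keep its ratio to the enzymes, and that ratio over the one in retained cells had a median of 0.721 (1.10 at day 2 and 0.465 at day 4), with 4 of 10 libraries below the range of 0.5 to 2 set beforehand and 1 above it, so carry-over and own transcripts cannot be told apart. Uptake of labelled cells, infection of macrophages and autofluorescence remain open and were not tested.

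Gip, a gut hormone gene, held 11% of the UMIs at day 10, above the 5.81% of Ins2. Between 69.8% and 75.0% of the retained cells of each day 10 library had at least 1% of their UMIs from Gip, so a few extreme cells are not its source. As free RNA it would reach other cells alike, but macrophage-like cells held at most 7.50% of the Gip share of retained cells in any day 6 library, and the 10 such cells of day 10 a median of 1.90%. At day 4 the median Gip share of retained cells was 0.0801% to 0.382% per library. Macrophage-like cells held 4.61% to 89.1% of the share of retained cells at day 4 and 117% to 395% at day 2, so carry-over stays open for those days. With batch as a term, Gip still rose from day 2 to day 4 by log2 6.11 (edgeR adjusted p = 1.01e-09). A hypothesis is that Gip is transcribed in most of the retained cells at day 10, and it was found and tested in the same data.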

How the results depend on the processing

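The retained clusters, the same without a further cluster, the removal of Rn45s and mitochondrial genes, batch as a term, the day 1 batches taken singly, the compared days alone and the leave-one-out of transient genes were chosen after the data were seen; the rest were set before. DESeq2's size factors, at least 1500 detected genes, the removal of Rn45s and mitochondrial genes, of acinar enzymes and insulin genes, unthinned cells and a limit of 2 markers of other types changed no call or direction among the results tried. The fry test kept every list called by camera and called 17, 14, 16, 20, 22 and 17 lists from day 1 to day 10 against day 0. Dropping the cell filter is void, since the filter removes 0 cells. Genes without a call that changed sign and stayed without one were counted as unchanged. Leaving out cells with 3 markers of other types left no library of day 2 and 1 of day 4, so it gave no value for their contrasts.

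Without a scaling factor the counts of called genes moved to 11057 at day 1, 11630 at day 2, 12352 at day 4, 12737 at day 6, 12666 at day 8 and 12493 at day 10 against day 0, to 362 from day 4 to 6 and 42 from day 8 to 10. The lists whose direction reversed without scaling were oxidative phosphorylation (camera adjusted p = 0.776 at day 1, 5.90e-12 at day 6, 1.32e-10 at day 8 and 9.10e-11 at day 10), ribosomal proteins (0.000115 at day 2, 0.00106 at day 4), the unfolded protein response (0.732, 0.946 and 0.984 at days 6, 8 and 10), insulin and granule cargo (0.737 at day 4), and other hormones and interferon response (0.703 and 0.657 at day 8). With an estimated correlation 8 lists were called at day 1 and 4 at each later day, against 14, 10, 12, 14, 16 and 13 of 24 with the preset one.

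Cells thinned before summing gave 4392 genes at day 8 and 4396 at day 10 against day 0, with fewer counts to test on. Leaving out cells with 3 markers of other types gave 3842 genes at day 1, 20 from day 6 to 8 and 14 from day 8 to 10. The retained clusters, with or without the further cluster, gave 6 from day 8 to 10. DESeq2's Wald test gave 102 from day 6 to 8 and 150 from day 8 to 10. Batch as a term left 194 from day 4 to 6 and 1 from day 6 to 8, and gave 103 from day 8 to 10. The replicate block, although numbers do not pair libraries, gave 39 there. The compared days alone gave 4700 for day 2 against day 0, then 2732, 2014, 1547, 95 and 239 over the steps in order. The causes of these changes were not tested. At day 4, the 1 gene of insulin-high cells became 77 with no low-count filter, 88 with DESeq2 and 0 with the upper and lower quartile.

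Leaving out 1 library at a time gave 453 to 777 genes from day 4 to 6, 16 to 59 from day 6 to 8, 9 to 94 from day 8 to 10, and 1 to 4 for insulin-high cells at day 4. The lowest value from day 4 to 6 and the 459 next to it came without a day 6 library of batch D each. From day 6 to 8 the number was 17 and 26 without day 6 replicates 1 and 3, and 26, 16, 21, 21 and 27 without day 8 replicates 1 to 5. From day 8 to 10 it was 29, 26 and 26 without day 8 replicates 1, 3 and 4, and 33, 27, 10 and 9 without day 10 replicates 2 to 5. For insulin-high cells it was 4 and 3 without day 4 replicates 3 and 5. Calls among few genes near the threshold thus rest on single libraries.

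Per cell, the difference in cells with an insulin UMI between days 2 and 0 passed at 3 UMIs or more (37.9 points, though 40.95% of the macrophage-like cells of day 2 had as many against 39.8% of all cells, so not above background), as did that between days 4 and 0 (27.9), at the lower depth (33.2), and without day 0 replicate 2 (47.5, range 30.6 to 47.5). That between days 8 and 6 passed without cells with 3 markers of other types (9.07) and without day 6 replicate 1 (9.71, range 4.83 to 9.71). The fall of the acinar share at day 1 was lost without cells with 3 markers (-3.37 points) and reversed in the retained clusters (0.335). There the next steps became calls at -13.3, -24.1 and -3.88 points. That set keeps cells of days 1 and 2 mostly in clusters named for acinar enzymes, so it cannot decide on the day 1 fall. From day 4 to 6 the fall also passed without day 4 replicate 5 (-2.50, range -2.50 to -1.30). In the retained clusters the mean rho of acinar and granule shares changed sign to 0.0132 at day 1, -0.165 at day 2, -0.0201 at day 4, -0.177 at day 6 and -0.121 at day 8. Over all cells, with Ins1 and Ins2 alone it was 0.239 at day 4 and -0.102 at day 8.

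Of named genes, Ins1 and Ins2 reversed from day 0 to day 1 without cells with 3 markers (log2 -5.83 and -7.11) and from batch H alone (-6.21 and -7.12), and from day 1 to day 2 in the retained clusters (1.78 and 1.79), without the further cluster (1.77 and 1.76) and with batch H alone (8.31 and 7.94). Reg2 and Rnase1 reversed from day 6 to day 8 with batch as a term (0.27 and 0.18). Ins2 turned to log2 -1.05 at day 1 against day 0 in the retained clusters, without a call in either set. Over results of genes and lists together, 57 lost and 3 gained a call and 1321 did neither without 1 library. The numbers lost, gained and unchanged were 21, 4 and 190 without scaling, 9, 5 and 199 in the retained clusters, 8, 5 and 101 there without the further cluster, 6, 1 and 88 without cells with 3 markers, 8, 0 and 34 with batch as a term, 3, 0 and 123 with cells thinned before summing, and 51, 0 and 28, lists alone, with an estimated correlation.

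For all 11 contrasts, 40 draws of splits of the libraries of both days held no other split with as many genes, a share of 1 in 40. This counts against chance only if the libraries are independent of each other. Whether 1 mouse gave more than 1 library is not given, so chance differences between mice stay open. The numbers of genes come from fits of the compared days alone, not from the fit of all days. The splits did not keep batches, so they say nothing on batch. The real numbers were 4364, 4700, 6135, 6184, 6618 and 6698 against day 0 and 2732, 2014, 1547, 95 and 239 over the steps, and the highest other was 1, from day 4 to 6 and day 6 to 8, and 0 elsewhere. For transient genes it was 131 against 2723 over 40 draws. The 16 sign changes of 5 pairs cannot give a share under 0.05; the real numbers were 1 at day 4, where the highest other was 4 and 2 of 16 gave as many, and 1572 at day 10, where the highest other was 1. Low counts limit Mafa, whose mean over all cells stayed below 50 CPM on each day.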

Other observations

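The ghrelin test and the genes below were chosen after the clusters were seen; the Gip and insulin test was set before. Over thinned cells of the retained clusters, the Ghrl count correlated with that of acinar enzymes in 15 of 15 libraries of days 6 to 10 (mean rho 0.281 ± 0.104). A cluster led by Ghrl, Rbpjl and Ptf1a had prompted this test on the same cells, so it is void and decides nothing. For the same reason no test is given for Rbpjl, the acinar factor, at 3.74 CPM at day 4 and 28.4 ± 32.6 at day 6 in these clusters, and its partner Ptf1a, at 10.0 and 31.8 CPM.

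Whether Gip and insulin rise in the same cells was asked within libraries of days 6 to 10. Over retained cells, their shares of the other UMIs correlated positively in 12 of 15 libraries (mean rho 0.0933 ± 0.124), and in 2, 5 and 5 of 5 at days 6, 8 and 10. Their shares of all UMIs did so in 8 of 15 (mean rho 0.0104 ± 0.122), and in 0, 5 and 3 of 5. The answer thus depends on the total used, and a joint rise and none cannot be told apart.

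Genes that led 1 cluster were followed over the retained clusters from day 0 to day 10. That cluster holds no day 0 cell, so a test of these genes would repeat what chose them, and none is given. Mcidas went from 0 to 11.3 ± 8.30 CPM, Deup1 from 0 to 9.93 ± 9.68, Rsph1 from 2.05 to 40.3 ± 22.9 and Ccno from 2.91 to 14.9. Gcg averaged 131 ± 291 CPM at day 4. Sst averaged 84.7 ± 189 at day 6, 135.5 ± 204.4 at day 8 and 0.586 ± 0.735 at day 10. These spreads all lay above their means.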
